A study of Mus musculus with 6 samples.

How the data were processed

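Total RNA from the proximal region of the incisor of 6-week-old C57BL/6 mice was sequenced in 6 libraries, 3 per genotype. Per the labels' protocols, tamoxifen was injected at 1.5 mg per 10 g body weight on 3 days at 1 month of age, RNA integrity numbers were above 9.0, and single-end reads of 75 cycles were made on a NextSeq500. Per the submitters' processing notes, STAR 2.6.1d and Partek were used with the mouse genome build mm10. The annotation release, the library kit and the strand setting are not given in the sources used here. Replicate numbers in the text follow accession order within each genotype and name libraries only.

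The authors deposited a table of estimated counts for 25703 genes, which are not whole numbers for every gene (54% to 57.6% of the values of a library lie within 0.01 of a whole number). Each gene in it has a total of at least 10. The authors also deposited a normalized signal table of 21456 genes. Tested on the values, each entry equals the count plus 1 divided by a single factor for its library, to within 0.00067%, and the upper quartiles of the 6 libraries lie between 35.97 and 35.98. The method of that normalization is not given in the sources used here. Both tables hold 6 sample columns and no column of another sample. Of the gene symbols, 25060 (97.5%) are in GENCODE release M21, with the same start in 99.4% of them, and the deposited stop lies 1 base past its end in 99.3%, so ends are printed as the stop minus 1.

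Estimated counts were rounded to whole numbers. Genes were kept with filterByExpr of edgeR (minimum count 10), which left 19613, library sizes were normalized by TMM, and genotypes were compared with the quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest, two-sided) without covariates. P-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as threshold, and SE is the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 15.8%. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used. CPM values use TMM-scaled library sizes. TMM factors ranged from 0.961 to 1.04.

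Library totals were 27300932 to 37908478 counts, so for all but low genes the spread between libraries, more than counting error, limits the precision. No pair of libraries was alike within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts in the pair was at least 29.3 within groups and 50.6 between groups. Pearson correlations of log2 CPM (prior count 2) were 0.9783 to 0.9901 within and 0.9688 to 0.9835 between groups.

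The design was fixed before the data were examined, as were 36 gene lists, of which 34 had at least 5 measured members and were tested with camera (preset correlation 0.01), with an adjustment over the lists. The rule for named genes was also fixed. It takes Arid1a, Aurka, Cdk1 and Gli1, then the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 2 CPM, groups that do not overlap and a symbol that is not a clone, predicted gene or pseudogene name, and up to 4 members with the smallest p of each list named. Genes with near-identical copies, and genes that overlap another gene, are uncertain because reads could be split between them. Named genes that overlap a protein-coding gene on the opposite strand include Gli1 (Arhgap9), Col9a3 (Tcfl5), Aspn (Cenpp), Lipm (Ankrd22), Fgf2 (Nudt6), Lrig1 (Slc25a26), Acta1 (Gm20388) and Xist (Gm26992). On the same strand Foxm1 overlaps Tex52 and Gm44596, Foxf1 overlaps Gm20388, mt-Nd4 overlaps mt-Nd4l and mt-Atp8 overlaps mt-Atp6. Some other named genes overlap non-coding genes. Any other gene is said to be named after its value was seen. A result for 1 gene that the rule names is not reported here.

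The count test was tried on simulated counts drawn from the means, dispersions and library sizes of these libraries. With 50 genes changed at each of 4 folds, 30% of those changed 1.5-fold, 70% at 2-fold, 94% at 4-fold and 90% at 8-fold were recovered among 19313 genes tested, and 11 of 153 calls were not among the changed genes. With no gene changed, 0 of 19335 genes were called. Genes were drawn independently with the dispersions fitted here, so this check leaves out genes that vary together between libraries. It does not give the rate of false calls in the real data.

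Alternatives fixed beforehand were RLE, upper quartile and library size normalization, DESeq2, limma-voom, limma on the log2 of the authors' normalized table with pseudocounts 1, 0.5 and 5, no filter and a filter of 1 CPM in all libraries, counts not rounded, genes above 1% of the counts left out, robust estimation off, a fold of at least 1.5, each library left out in turn, and for lists an estimated correlation, fry and 10000 random lists matched on mean expression. Alternatives chosen after seeing the data were a term for sex-linked expression, only the 4 libraries with Y-linked counts, ribosomal RNA genes left out, a per-library trend on GC content and transcript length (natural splines with 3 degrees of freedom, GENCODE M21 transcripts) removed as an offset, and the mean score of the dental epithelium list as a covariate. No sample was left out of the main comparison. The titles also carry a number after the letter S, lower in every control than in every Arid1a cKO library and with gaps. What it stands for, and whether other libraries were made, is not given in the sources used here. If it reflects an order of handling, an effect of that order cannot be told apart from genotype.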

Results

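RNA from the proximal end of the mouse incisor was sequenced in 6 libraries, 3 from Arid1a fl/fl mice (control) and 3 from Gli1-CreER;Arid1a fl/fl mice (Arid1a cKO). The mouse incisor grows throughout life, and its proximal end holds the stem cells and the fast-dividing transit-amplifying cells that renew it. Gli1-CreER is a tamoxifen-inducible recombinase under the control of Gli1, a marker of mesenchymal stem cells of the incisor, and Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The comparison asks how loss of Arid1a in the Gli1 lineage alters transcription, and the title of the series directs attention to cell cycle exit and to the kinases Aurka and Cdk1. The estimated counts summed to 32677240, 27324259 and 27300932 in control replicates 1 to 3. They summed to 37896883, 37908478 and 29922013 in Arid1a cKO replicates 1 to 3. Nothing in the labels states that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. It is not technical alone, as sex-linked counts (given at the end) show animals of both sexes in each group.

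Arid1a, the targeted gene (chromosome 4, 133679008 to 133756769, mm10, minus strand, protein coding), was lower in all 3 Arid1a cKO libraries. Its level was 222, 249 and 223 CPM (counts scaled to the library size) in control replicates 1 to 3 and 136, 139 and 145 CPM in Arid1a cKO replicates 1 to 3. Mean levels were 231 ± 15.2 CPM (SD, n = 3) in control and 140.2 ± 4.57 CPM (SD, n = 3) in Arid1a cKO, a 1.65-fold lower level (log2 fold change -0.72, SE 0.0677, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00802). The count covers the whole gene, including parts outside the floxed exons, and cells outside the Gli1 lineage keep the gene. Among the 26 measured SWI/SNF subunits Arid1a was the 1 member past the threshold. The members with the next smallest p were Bcl7a (log2 fold change 0.22, adjusted p = 0.121 by edgeR), Dpf3 (0.75, 0.146) and Smarca2 (-0.18, 0.172), and the list as a whole had a camera adjusted p of 0.745.

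**Figure D1:**
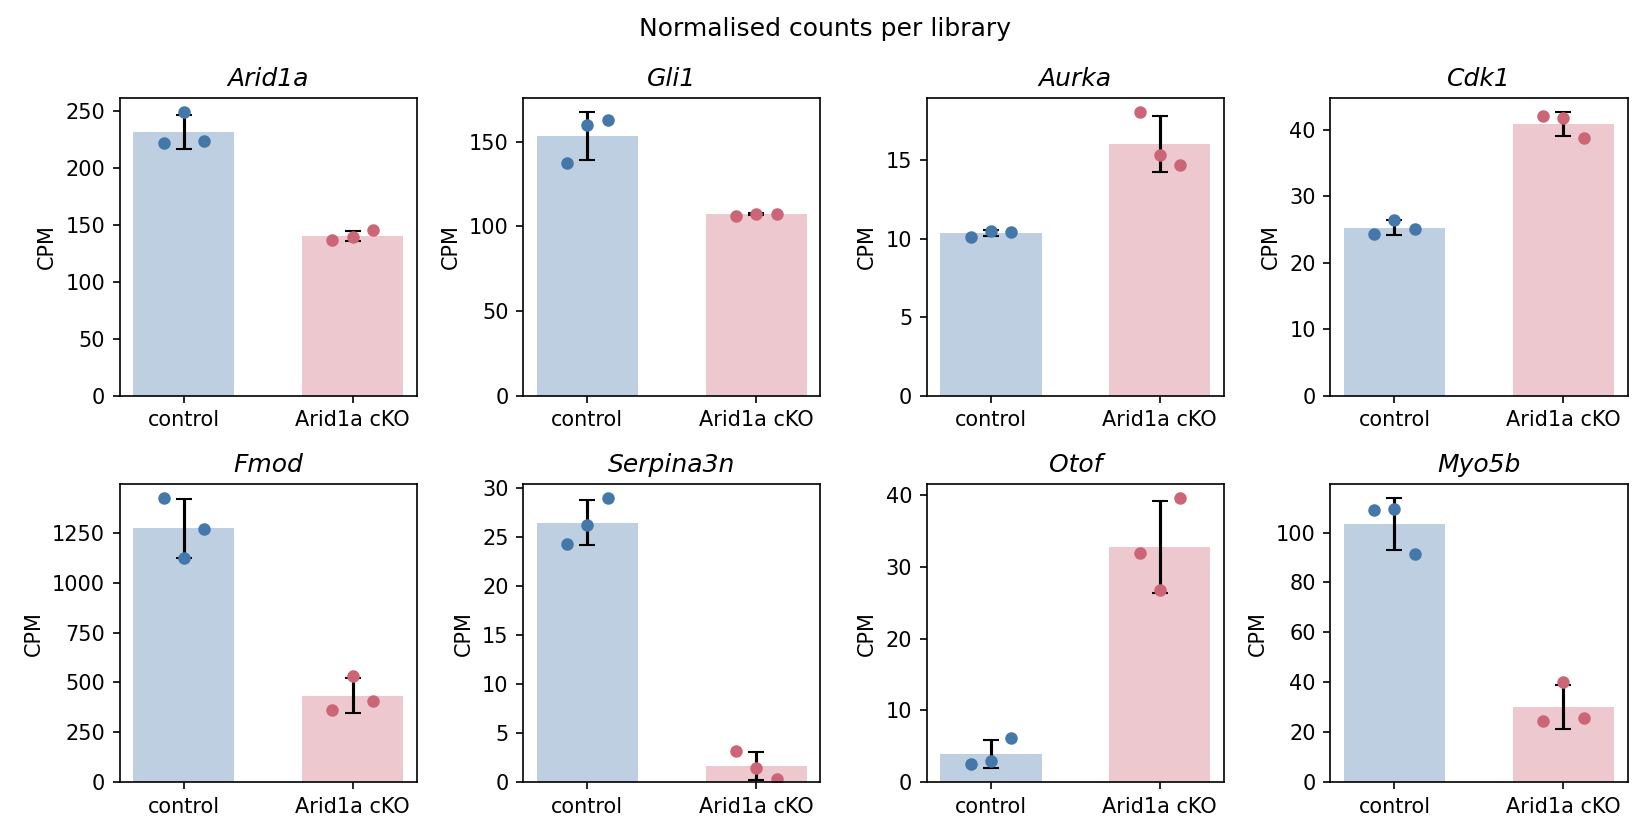
CPM in each library for 8 genes. Bars are group means, error bars SD (n = 3 per group) and points single libraries. In every panel the 3 control points and the 3 Arid1a cKO points do not overlap, with Arid1a at 222 to 249 CPM in control and 136 to 145 CPM in Arid1a cKO.

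More genes were lower than higher in Arid1a cKO. Of 19613 genes tested, 777 differed between the groups at an adjusted p under 0.05 in the edgeR quasi-likelihood test. In Arid1a cKO 295 were higher and 482 lower. A fold of at least 2 was reached by 90 of the higher and 81 of the lower genes, and the median absolute log2 fold change of the 777 genes was 0.61. The 3 control and 3 Arid1a cKO values were fully separate in each of the 777 genes. They were also separate in 5705 of all genes tested (29.1%, against 10% by chance for 3 against 3). The first principal component held 40.4% of the variance and separated the groups, with controls at -40.2, -29.1 and -12.8 and Arid1a cKO at 52.4, 10.4 and 19.4. The second (23.1%) did not, with controls at 16.1, -7.44 and 20.5 and Arid1a cKO at 29.6, -31.5 and -27.3. Arid1a cKO replicates 2 and 3 correlated more with control replicate 2 (Pearson 0.9835 and 0.9834) than with Arid1a cKO replicate 1 (0.9783 and 0.9814). The count of genes was not stable to the test or to the libraries. DESeq2 called 1935 genes. Leaving out control replicate 1, 2 or 3 gave 160, 352 and 187 genes, and leaving out Arid1a cKO replicate 1, 2 or 3 gave 532, 433 and 165. With the dental epithelium score as a covariate, chosen after seeing the data, 4 genes passed. All of the 777 genes kept their sign in these fits where they had a value. As their groups were fully separate, leaving out a library could hardly reverse a sign.

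**Figure D2:**
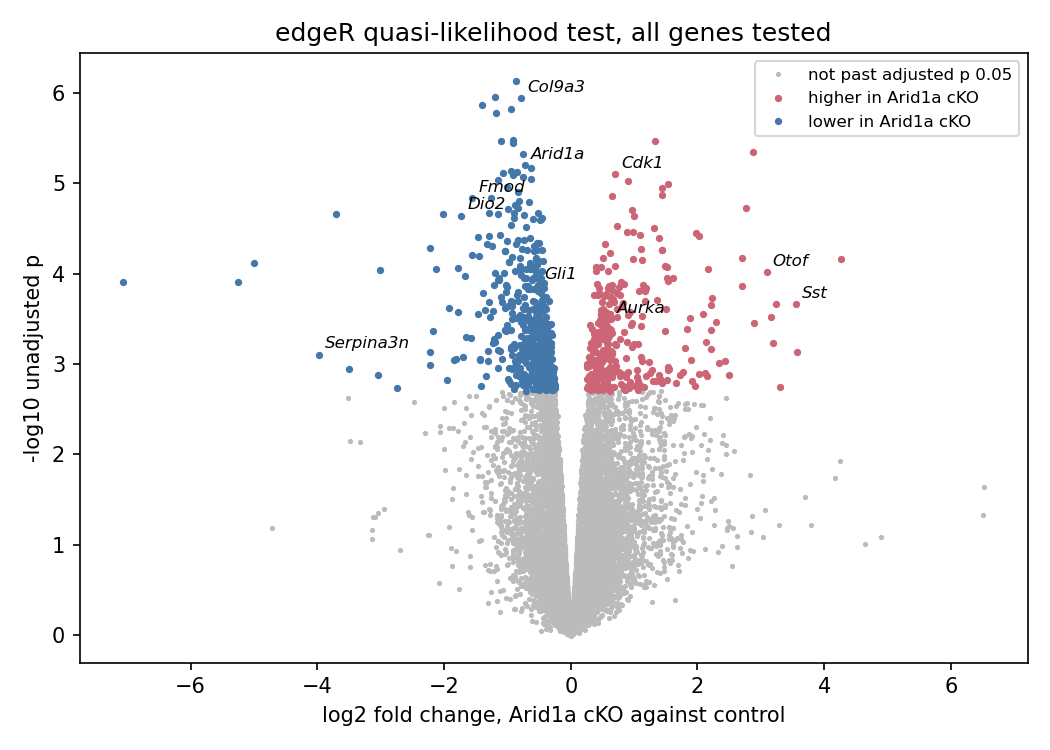
Each point is a gene tested, with the log2 fold change of Arid1a cKO against control on the x axis and -log10 of the unadjusted edgeR p on the y axis. Coloured points are the 295 higher and 482 lower genes past an adjusted p of 0.05.

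A part of the genes of the dividing cell, 36 of 108 in 3 lists, was higher in Arid1a cKO, and 0 were lower. Cdk1, the kinase that drives entry into mitosis (chromosome 10, 69335146 to 69352938), rose 1.62-fold, from 25.3 ± 1.1 to 40.9 ± 1.78 CPM (SD, n = 3; log2 fold change 0.69, SE 0.0671, edgeR adjusted p = 0.00802). Aurka, a mitotic kinase of centrosomes and spindle (chromosome 2, 172356190 to 172370535), rose 1.55-fold, from 10.4 ± 0.201 to 16.0 ± 1.79 CPM (SD, n = 3; log2 fold change 0.63, SE 0.103, edgeR adjusted p = 0.0215). Both kinases are named in the title of the series and may have been chosen on these samples, so they are not independent evidence of a direction. With the dental epithelium score as a covariate, chosen after seeing the data, neither kinase passed (adjusted p = 0.318 for Aurka and 0.1 for Cdk1). Their log2 fold changes were then 0.54 (SE 0.16) and 0.69 (SE 0.107). The Aurka call was lost without control replicate 1 (adjusted p = 0.081), 2 (0.0566) or 3 (0.0775) and without Arid1a cKO replicate 3 (0.0529), while the Cdk1 call held without each library in turn (adjusted p from 0.0101 to 0.039).

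Of 54 measured G2/M phase genes, 23 rose and 0 fell, and 43 rose when p-values were adjusted over the list alone, with a median log2 fold change of 0.46. Examples were the microtubule regulator Psrc1 (1.98-fold, edgeR adjusted p = 0.0116), the DNA topoisomerase Top2a (1.47-fold, 0.0171) and the chromosomal passenger protein Birc5 (1.47-fold, 0.0203). Of 43 S phase genes 10 rose and 0 fell (30 and 0 over the list alone, median 0.36), including the replication clamp Pcna (1.31-fold, adjusted p = 0.0142), the ribonucleotide reductase subunits Rrm1 (1.34-fold, 0.0175) and Rrm2 (1.53-fold, 0.0208), and Uhrf1, which maintains DNA methylation (1.42-fold, 0.0199). Of 16 Aurka-Cdk1 mitotic entry kinases and regulators, a list that follows the title of the series, 6 rose and 0 fell (11 and 0 over the list alone), among them Plk1 (1.59-fold, 0.0183) and the transcription factor Foxm1 (log2 fold change 0.48, 0.0207). Together these 3 lists hold 108 genes, of which 36 rose, 0 fell and 103 had a positive log2 fold change. Of the examples, Psrc1 passed without each library in turn. Pcna was lost without control replicate 3. Top2a, Rrm1 and Uhrf1 were lost without control replicate 1 or 3. Birc5 was lost without these or Arid1a cKO replicate 2, and Rrm2 without any of these or control replicate 2. Plk1 was lost without control replicate 1 or 3 or Arid1a cKO replicate 3, and Foxm1 without any of these or Arid1a cKO replicate 2 (adjusted p of up to 0.0807). The number of G2/M genes that rose was 39 with DESeq2. It was 2, 12 and 2 without control replicate 1, 2 or 3 and 10, 4 and 10 without Arid1a cKO replicate 1, 2 or 3, with medians from 0.425 to 0.544. With the dental epithelium score it was 0, at a median of 0.426. The S phase number was 25 with DESeq2. It was 1, 3 and 0 without control replicate 1, 2 or 3 and 5, 3 and 5 without Arid1a cKO replicate 1, 2 or 3. For mitotic entry the numbers without the same libraries in order were 1, 5, 1, 4, 3 and 2, against 10 with DESeq2.

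As whole lists, G2/M (camera adjusted p = 3.44e-29), S phase (1.65e-16) and the mitotic entry list (6.68e-11) passed, and each had an adjusted p of 0.344 with an estimated correlation. Camera with its preset correlation also passed 10 to 20 of the 34 lists tested in each of the 9 other splits of the 6 libraries, against 17 in the real split, and passed G2/M in 7 of them, with an adjusted p as small as 9.55e-31. A camera p is therefore given below as a description of a list and not as evidence that it differs between the genotypes. The rotation test fry, which does not compare a list with other genes, passed 6 lists in the real split and 0 in each other split: G2/M (adjusted p = 0.0399), S phase (0.0371), mitotic entry (0.0371), collagens (0.00153), cartilage (0.0106) and BMP and TGF-beta targets (0.0397). Some of these lists share genes, so the passes are not separate results. G2/M and mitotic entry share Aurka, Cdk1 and others, and collagens and cartilage share Col9a2, Col9a3 and others. Each other split holds both genotypes in each group, so a genotype difference adds to its spread and partly stays in its contrast. The 0 with fry thus does not show how often lists pass with no difference, and some camera passes there may stem from genotype. In each of these 3 cell cycle lists the mean score of every Arid1a cKO library was above that of every control library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The same held downward for cartilage and for BMP and TGF-beta targets, but not for collagens, where control replicate 1 (-0.04) lay below Arid1a cKO replicate 1 (0.0068; exact permutation p = 0.2). Scores were also fully separate, upward, in lists that fry did not pass: ribosomal proteins, histones, p53 targets and immediate early genes. The same was true of the neutrophil genes, too few to test. Separate scores are thus not particular to the lists that fry passed.

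**Figure D3:**
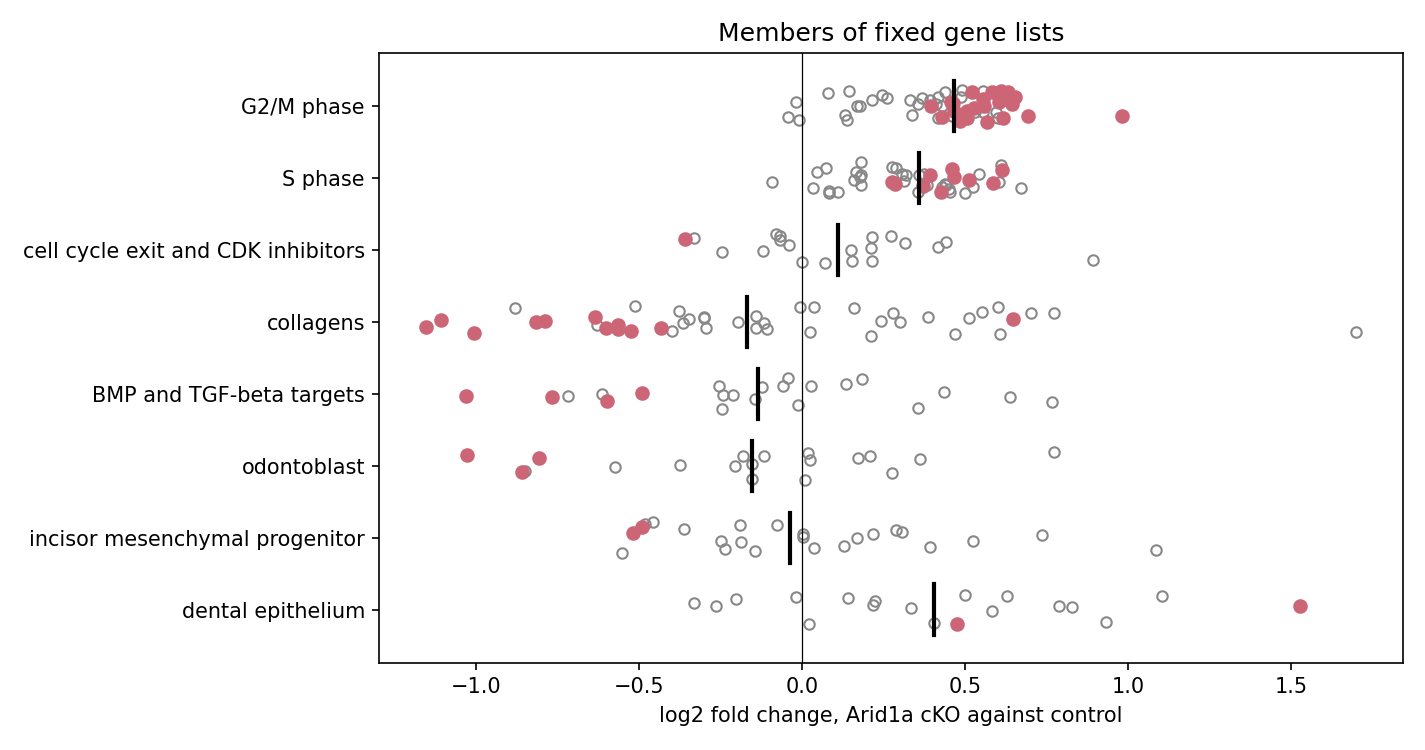
Log2 fold change of each measured member of 8 gene lists, with filled points past an adjusted p of 0.05, open points not past it, and black bars at the median. The G2/M and S phase points lie mostly to the right of 0, with medians of 0.46 and 0.36, while the filled collagen points lie to the left except Col8a1.

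Genes of cell cycle exit did not fall as a group. Of 20 measured genes, 1 passed the threshold: the CDK inhibitor Cdkn1b fell 1.28-fold, from 149.9 ± 3.07 to 117 ± 7.64 CPM (SD, n = 3; edgeR adjusted p = 0.0274). The CDK inhibitors Cdkn1a (log2 fold change 0.42, adjusted p = 0.0872), Cdkn2d (0.27, 0.143) and Cdkn2c (0.22, 0.176) did not pass, and the list had a camera adjusted p of 0.552. None of 20 p53 targets passed over all genes by edgeR, and 7 were higher and 1 lower over the list alone (camera adjusted p = 0.00169, and 0.482 with an estimated correlation). Those with the smallest p were Rps27l (log2 fold change 0.31, adjusted p = 0.0507), Plk2 (0.40, 0.0537), Zmat3 (0.27, 0.0574) and Pmaip1 (1.41, 0.0755). The 17 replication-dependent histone genes, near-identical copies whose reads cannot be assigned with certainty, had a median log2 fold change of 0.71 with 0 past the threshold by edgeR (camera adjusted p = 0.000129, and 0.344 with an estimated correlation). Their mean score was -0.84, -0.22 and -0.17 in control replicates 1 to 3. In Arid1a cKO replicates 1 to 3 it was 0.25, 0.58 and 0.4. This ranks the libraries exactly as their ribosomal RNA share does (given below). The histone rise cannot be told apart from that difference here. The Cdkn1b call was lost without control replicate 1, 2 or 3 or Arid1a cKO replicate 3, with an adjusted p of up to 0.105.

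Of 44 measured collagens, 11 fell, 1 rose and 32 did not pass in Arid1a cKO, and over the list alone 13 fell and 3 rose (median log2 fold change -0.17; camera adjusted p = 2.95e-05, and 0.182 with an estimated correlation). The microfibrillar collagen genes Col6a2 and Col6a1 fell 2.23-fold (792.5 ± 82.1 to 356 ± 38.9 CPM, SD, n = 3, edgeR adjusted p = 0.00802) and 2.01-fold (755 ± 41 to 375.5 ± 42.7 CPM, SD, n = 3, adjusted p = 0.00839), Col5a3 fell 2.15-fold (adjusted p = 0.00697) and Col9a3 fell 1.73-fold (adjusted p = 0.00537). These 4 held without each library in turn. Col8a1 was the collagen that rose (1.57-fold, adjusted p = 0.0162; named after its value was seen). Of 11 cartilage genes 3 fell and 0 rose (7 and 2 over the list alone): Col9a3, Col9a2 (1.48-fold, 0.0199) and the transcription factor Sox9 (1.47-fold, 0.0138), while Cnmd missed the threshold (log2 fold change -1.84, adjusted p = 0.0559). The cartilage list had a camera adjusted p of 0.000131, and 0.198 with an estimated correlation. Leaving out control replicate 1, 2 or 3 gave 5, 7 and 6 collagens lower, leaving out Arid1a cKO replicate 3 gave 5, and the dental epithelium score as a covariate gave 0, with a median of -0.172 over the list against -0.169 without it. For cartilage that score gave 0 genes lower and a median of -0.224 against -0.511. With a filter of 1 CPM in all libraries the collagen median was -0.28. DESeq2 called 15 collagens lower and 4 higher, and 6 cartilage genes lower and 1 higher. Sox9 was lost without Arid1a cKO replicate 3 (adjusted p = 0.0525), and Col9a2 without this library or control replicate 1 or 2 (up to 0.0685).

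Among markers of dental follicle and periodontal ligament, the tissues around the tooth, 3 of 12 fell and 0 rose (4 and 1 over the list alone). The small proteoglycan Fmod fell 2.94-fold, from 1273 ± 149 to 433 ± 88.9 CPM (SD, n = 3, edgeR adjusted p = 0.00919), Col12a1 fell 1.48-fold (0.0217) and Aspn fell 1.58-fold (0.0376), and Pthlh had a log2 fold change of 0.35 (0.0687). The list had a median of 0.09, a mean of -0.05 and a camera adjusted p of 0.41 in the downward direction. Of 19 odontoblast genes, expressed by the cells that form dentin, 3 fell and 0 rose over all genes and over the list alone: the vitamin D receptor Vdr (2.04-fold, 0.0162), the intermediate filament gene Nes (1.82-fold, 0.0359) and the phosphatase Alpl (1.75-fold, 0.0379). Col24a1 had a log2 fold change of 0.77 (adjusted p = 0.119), and the list had a camera adjusted p of 0.0835. The Fmod call held without each library in turn, and 1 or more of the calls of Col12a1, Aspn, Vdr, Nes and Alpl was lost without each of the 6 libraries, with adjusted p of up to 0.123. The odontoblast list depended on single libraries: without control replicate 1, 0 genes fell, 1 rose and the median turned from -0.155 to 0.0438, and without control replicate 2 the list passed camera (adjusted p = 6.8e-06). Aspn overlaps Cenpp on the opposite strand and was also lost with limma-voom, with limma on the authors' normalized table and with the GC and length trend removed. Nes was also lost with that trend removed, and Alpl with limma on the authors' table at a pseudocount of 5.

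Signalling genes moved in both directions. Gli1, a transcription factor of Hedgehog signalling (chromosome 10, 127329882 to 127341974), fell 1.43-fold, from 153 ± 14.1 to 107 ± 0.559 CPM (SD, n = 3; log2 fold change -0.52, SE 0.0747, edgeR adjusted p = 0.0162). By the genotype labels the CreER allele was present in Arid1a cKO alone, and whether it disrupts a copy of Gli1 is not given in the sources used here. Gli1 overlaps Arhgap9 on the opposite strand, and the strand setting of the counts is not given in the sources used here. In the Hedgehog list, 1 of 18 genes fell and 1 rose (2 and 1 over the list alone). Gli1 was the gene that fell, and Foxf1 (log2 fold change -0.24, adjusted p = 0.0767) and Cdon (0.47, 0.157) did not pass (camera adjusted p = 0.573). In the incisor mesenchymal progenitor list 2 of 24 fell and 0 rose (5 and 2 over the list alone): Gli1 and the homeobox gene Msx2 (log2 fold change -0.49, 0.0194), with Prrx2 (log2 fold change -0.46, 0.0642) and Lhx6 (-0.48, 0.0868) not past it (camera adjusted p = 0.285). The Gli1 call was lost without control replicate 2 or 3 or Arid1a cKO replicate 3, with an adjusted p of up to 0.0674. Msx2 was lost without control replicate 3 or Arid1a cKO replicate 2 or 3 (up to 0.0667).

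Of 22 BMP and TGF-beta targets 4 fell and 0 rose (7 and 1 over the list alone; camera adjusted p = 0.00169, and 0.344 with an estimated correlation). These were the BMP antagonist Nog (2.04-fold, edgeR adjusted p = 0.0127), the matrix protein Tgfbi (1.70-fold, 0.0211), Msx2 and the ligand Bmp2 (1.52-fold, 0.0294). In the FGF list 2 of 18 fell and 2 rose (2 and 6 over the list alone; camera adjusted p = 0.184): the receptor Fgfr3 fell 2.35-fold (0.0202) and the ligand Fgf2 fell 1.29-fold (0.0392), and the FGF-responsive genes Etv5 (1.42-fold, 0.0274) and Spry1 (1.34-fold, 0.0495) rose. In the Wnt list 2 of 19 fell and 0 rose (2 and 2 over the list alone; camera adjusted p = 0.603): Dkk3 fell 1.37-fold (0.00949) and the ligand Wnt5a fell 1.61-fold (0.0341), while Dkk1 (log2 fold change 0.93, 0.0725) and Wnt11 (1.11, 0.0821) did not pass. Dkk3 held without each library in turn, Fgf2 was lost without each (adjusted p from 0.0726 to 0.115) and with upper quartile or library size normalization, and Nog was lost without control replicate 3 (0.0512). Etv5 and Fgfr3 were lost without each control or Arid1a cKO replicate 3 (up to 0.0806), Spry1 also without Arid1a cKO replicate 2 (up to 0.135) and with limma-voom, and Wnt5a without each library except Arid1a cKO replicate 2 (up to 0.108). Fgf2 and Spry1 were also lost with limma on the authors' normalized table, and Spry1 with robust estimation off and with the GC and length trend removed. The log2 fold change of Nog, -1.03, was -0.635 on that table with a pseudocount of 5. The number of BMP and TGF-beta targets that fell was 2, 2 and 1 without control replicate 1, 2 or 3 and 4, 2 and 1 without Arid1a cKO replicate 1, 2 or 3. It was 7 with DESeq2 and 0 with the dental epithelium score, where the median was -0.12 against -0.134 without it.

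The 10 largest rises that met the rule for named genes were in genes of different kinds. Somatostatin (Sst, chromosome 16, 23889573 to 23890958) rose 11.7-fold but stayed low, from 0.366 to 4.28 CPM (log2 fold change 3.55, SE 0.519, edgeR adjusted p = 0.019). The synaptic vesicle protein Otof (chromosome 5, 30367062 to 30461932) rose from 3.86 ± 1.95 to 32.8 ± 6.4 CPM (SD, n = 3; 8.52-fold, adjusted p = 0.0145). The serotonin receptor Htr1a rose 9.11-fold (adjusted p = 0.0287), the GABA receptor subunit Gabra3 7.40-fold (0.0228), the GABA transporter Slc6a13 3.71-fold (0.0215) and the potassium channel partner Kcnip2 3.57-fold (0.0245). Lipm rose 6.50-fold (0.0163), Cd209f 5.05-fold (0.0356) and Aldh1a7 4.09-fold (0.0119). The 5.8S ribosomal RNA gene n-R5-8s1, a multicopy gene whose reads cannot be assigned with certainty, rose 4.34-fold (0.0402). Cd209f and Aldh1a7 have close paralogs, so reads shared between copies add uncertainty to both. Gabra3, Cd209f and n-R5-8s1 did not pass with limma-voom, and the log2 fold change of Htr1a, 3.19, was 3.86 without control replicate 2. At these low levels the size of a rise depended on the pseudocount: on the authors' normalized table with a pseudocount of 5 the log2 fold change was 0.66 for Sst, 0.61 for Htr1a, 0.83 for Lipm, 0.87 for Gabra3 and 0.77 for Kcnip2. It was 1.975 for Otof, 0.74 for Cd209f, 0.74 for n-R5-8s1, 0.80 for Aldh1a7 and 0.49 for Slc6a13. With the dental epithelium score that of Sst was 2.16.

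The genes that fell most included Serpina3n, a secreted protease inhibitor (chromosome 12, 104406729 to 104414329), which fell 15.8-fold, from 26.5 ± 2.34 to 1.62 ± 1.41 CPM (SD, n = 3; log2 fold change -3.98, SE 0.614, edgeR adjusted p = 0.0329) and also has close paralogs. Its log2 fold change was -4.84 without Arid1a cKO replicate 1 and -2.08 on the authors' normalized table with a pseudocount of 5. Its call was lost with no filter (0.0534), without each control (0.0885 to 0.102) and without Arid1a cKO replicate 2 (0.102). The motor protein Myo5b fell 3.45-fold, from 103 ± 10.4 to 30 ± 8.72 CPM (adjusted p = 0.0142), and Dio2, which activates thyroid hormone, fell 3.31-fold, from 74.8 ± 14.9 to 22.6 ± 3.48 CPM (adjusted p = 0.00948). Unc80 fell 4.65-fold (0.0321), the long non-coding RNA BC055402 4.35-fold (0.0142), Tnfaip2 3.81-fold (0.0198), the ciliary neurotrophic factor receptor Cntfr 3.59-fold (0.0347), Sgsm1 3.20-fold (0.015) and the axonal growth protein Gap43 3.15-fold (0.0267). On the authors' normalized table with a pseudocount of 5 the log2 fold change went from -2.22 to -1.02 for Unc80, from -2.12 to -0.63 for BC055402, from -1.68 to -0.64 for Sgsm1 and from -1.655 to -0.89 for Gap43. Of the 24 genes named in these groups and above by a fixed rule, 10, 12 and 10 passed without control replicate 1, 2 or 3 and 21, 13 and 8 without Arid1a cKO replicate 1, 2 or 3, and all 24 kept their sign. Their groups did not overlap, so a change of sign was hardly possible in these fits. Those that passed without each library in turn were Arid1a, Cdk1, Aldh1a7, Dio2 and Fmod.

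Of 83 ribosomal protein genes measured, 6 rose and 0 fell (23 and 1 over the list alone), among them Rpl30 (1.39-fold, edgeR adjusted p = 0.0142), Rpl24 (1.54-fold, 0.0244), Rpl6l (1.43-fold, 0.0347) and Rps21 (1.33-fold, 0.0372), genes with many near-identical copies in the genome. The median log2 fold change was 0.18 (camera adjusted p = 2.52e-10, and 0.527 with an estimated correlation), and fry did not pass the list (adjusted p = 0.0947). The gene CT010467.1, annotated as ribosomal RNA and named after its value was seen, took 0.864%, 1.01% and 1.05% of the counts in controls and 1.89%, 7.47% and 4.12% in Arid1a cKO (log2 fold change 2.20, adjusted p = 0.0667). This share was higher in each Arid1a cKO library than in each control, beside every gene group above, although the gene did not pass. With ribosomal RNA genes left out, chosen after seeing the data, 766 genes passed by edgeR, 741 of them among the 777. Of 54 G2/M genes 22 rose in that fit. Leaving these genes out does not remove effects that such a difference may have on other genes. All 15 mitochondrially encoded genes had a negative log2 fold change and 0 passed by edgeR (median -0.30; camera adjusted p = 0.000203, and 0.764 with an estimated correlation), the smallest p being at mt-Nd2 (log2 fold change -0.45, adjusted p = 0.084), mt-Nd4 (-0.41, 0.0901), mt-Nd3 (-0.45, 0.0945) and mt-Atp8 (-0.88, 0.129). Of 76 nuclear oxidative phosphorylation genes 1 fell, Cox4i2 (1.60-fold, 0.0163), while the median was 0.10 (camera adjusted p = 0.00104 upward, and 0.819 with an estimated correlation), and Atp5e (log2 fold change 0.29, 0.0637), Ndufs7 (0.34, 0.0662) and Ndufs8 (0.32, 0.0882) did not pass. The oxidative phosphorylation list was lost without control replicate 2 (0.0775) or Arid1a cKO replicate 1 (0.0852). With the GC and length trend removed, chosen after seeing the data, neither this list (0.223) nor the mitochondrially encoded list (0.0581) passed. Rpl30 was lost without Arid1a cKO replicate 3 (0.0525), Rps21 without each library (0.0519 to 0.105) and with library size normalization, Rpl24 and Rpl6l without control replicate 1 or 3 or Arid1a cKO replicate 2 or 3 (up to 0.126), and Cox4i2 without control replicate 1 or 3 (up to 0.0596).

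Markers of other cell types moved with the genotype in part. Of 19 dental epithelium genes 2 rose and 0 fell (3 and 0 over the list alone): the adhesion protein Epcam (1.39-fold, edgeR adjusted p = 0.0199) and the tight junction protein Cldn4 (2.88-fold, 0.0375, at 1.75 CPM), while Lrig1 (log2 fold change 0.93, 0.0767) and Sox2 (0.83, 0.107) did not pass (median 0.40; camera adjusted p = 0.000749, and 0.764 with an estimated correlation). Of 19 ameloblast genes, from the enamel-forming epithelium, 0 passed by edgeR (Klk4, log2 fold change 1.57, 0.0587; Cnnm4, -0.50, 0.107; camera adjusted p = 0.992). In skeletal muscle 1 of 10 genes fell, Casq1 (4.06-fold, 0.00948, from 2.42 to 0.598 CPM), and the median was -1.49 (camera adjusted p = 0.00991, and 0.764 with an estimated correlation), with Acta1 at 4.68 ± 6.09 and 0.539 ± 0.133 CPM (SD, n = 3). In the glia list Cdh19 fell 2.37-fold (0.0127) and the other 13 did not pass, among them Prx (log2 fold change 0.61, 0.096), although the median was 0.60 (camera adjusted p = 0.00991, and 0.808 with an estimated correlation). The glia list was lost without Arid1a cKO replicate 1 (0.102) and the muscle list without control replicate 2 (0.232), where its median was -0.483. Epcam was lost without each control or Arid1a cKO replicate 3 (up to 0.077), and Cldn4 without each library except control replicate 3 (up to 0.123). The median of the dental epithelium list was 0.203 without control replicate 1 and 0.191 without Arid1a cKO replicate 1. On the authors' normalized table with a pseudocount of 5 the log2 fold change was 0.23 for Cldn4 (1.53 by edgeR), -0.345 for Casq1 (-2.02 by edgeR) and -0.64 for Cdh19 (-1.25 by edgeR).

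Pericyte and smooth muscle genes moved both ways, 2 of 14 lower and 1 higher (4 and 2 over the list alone): Notch3 fell 1.35-fold (edgeR adjusted p = 0.0139), Pdgfrb fell 1.36-fold (0.02) and Myh11 rose 1.74-fold (0.0463; camera adjusted p = 0.77 for the list, whose median was -0.08 and mean 0.13). Of 11 bone and osteocyte genes, the Wnt antagonist Sost rose 2.91-fold (0.0156) and Cdh11 fell 1.31-fold (0.0496), with 2 higher and 3 lower over the list alone (camera adjusted p = 0.956 for the list, median -0.18, mean 0.04). Macrophage genes had 0 of 16 past the threshold by edgeR, all 16 with a positive log2 fold change (median 0.40; camera adjusted p = 0.00205, and 0.808 with an estimated correlation), and interferon response genes had 0 of 19, all 19 negative (median -0.34; camera adjusted p = 0.0126, and 0.819 with an estimated correlation). In the immediate early and stress list the transcription factor Egr2 rose 2.02-fold (0.0472), the 1 of 20 past the threshold (camera adjusted p = 0.015, and 0.482 with an estimated correlation). In edgeR 0 genes passed among the 17 endothelial (camera adjusted p = 0.992), 10 lymphocyte (0.573), 8 osteoclast (0.956), 7 stratified oral epithelium (0.814), 6 erythroid (0.956) and 5 sex-linked genes (0.992), and among 3 neutrophil and 4 adipocyte genes, too few to test as lists. At an unadjusted p under 0.05, 4307 genes of all kinds were counted. Without single libraries, macrophage genes were lost without control replicate 2 (0.0775) or Arid1a cKO replicate 1 (0.148). Interferon genes were lost without control replicate 1 (0.737) or Arid1a cKO replicate 2 (0.0847) or 3 (0.107), and immediate early genes without Arid1a cKO replicate 1 (0.0852). Myh11 and Cdh11 were lost without each library (adjusted p from 0.0724), and Cdh11 also with RLE, upper quartile or library size normalization, among other settings. Myh11 and Egr2 were also lost with library size normalization and with no filter, and Egr2 with robust estimation off and with the GC and length trend removed. On the authors' normalized table with a pseudocount of 5 the log2 fold change was 0.38 for Egr2 (1.015 by edgeR) and 0.67 for Sost (1.54 by edgeR). Notch3 was lost without control replicate 3 or Arid1a cKO replicate 3 (up to 0.0585), and Pdgfrb without either of these, control replicate 2 or Arid1a cKO replicate 2 (up to 0.077). Egr2 was lost without each except control replicate 2 (up to 0.137), and Sost without control replicate 1 or 3 or Arid1a cKO replicate 3 (up to 0.0616).

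Xist, expressed from the inactive X chromosome, was at 3890 CPM in control replicate 3 and 2810 CPM in Arid1a cKO replicate 1 and at 1.05 to 4.39 CPM in the other 4 libraries, and the Y-linked gene Ddx3y was at 66.2 to 93.8 CPM in those 4 libraries and at 0.0365 and 0.0255 CPM in the other pair. Each genotype thus held 1 library with the first pattern and 2 with the second. In the 4 libraries with Y-linked counts, a comparison of 2 against 2 chosen after seeing the data, 177 genes passed by edgeR, 54 higher and 123 lower. With a term for this difference in the model of all 6 libraries, also chosen after seeing the data, 1272 genes passed, 455 higher and 817 lower.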

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

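The alternatives with a term for sex-linked expression, only libraries with Y-linked counts, the ribosomal RNA genes left out, the GC and length trend removed and the dental epithelium score were chosen after seeing the data. No paired analysis was possible because the titles of the 2 groups share only the number 2, although the labels speak of pairs. Main counts were 777 genes, 295 higher and 482 lower. DESeq2 gave 1935 (831 and 1104), a fold of at least 1.5 left 413 (170 and 243), the sex-linked term gave 1272 (455 and 817), the 4 libraries with Y-linked counts gave 177 (54 and 123) and the epithelium score gave 4 (0 and 4), with 1888 at an unadjusted p under 0.05. Leaving out single libraries gave 160 to 532 genes, 55 to 193 higher and 98 to 339 lower, with fewer samples in each fit. The epithelium score leaves fewer residual degrees of freedom and shares 53.9% of its variance with the genotype. The sex-linked term, which also adds a covariate, gave more genes than the main test. What caused these changes, that with the epithelium score included, was not tested. Of the 777 genes, 768 were also called by DESeq2, and those with a value in a setting kept their main sign there. For fits without a single library this was nearly fixed, as the groups of these genes were fully separate.

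The log2 fold change of Arid1a was -0.70 with the epithelium score (adjusted p = 0.1), that of Cdk1 0.69 (0.1) and that of Aurka 0.54 (0.318), all no longer past the threshold. Aurka was at 0.55 in the 4 libraries with Y-linked counts (adjusted p = 0.0956) and between 0.54 and 0.70 without single libraries, where it was lost without each control or Arid1a cKO replicate 3. In the other alternatives these 3 genes stayed past the threshold. The lowest correlation between libraries, 0.9688, moved by less than the spread between pairs with a prior count of 0.5.

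The number of lists past the threshold was 17 in the main test, 0 with an estimated correlation and 6 with fry. With an estimated correlation the adjusted p was 0.344 for G2/M, S phase, mitotic entry, BMP and TGF-beta targets and histones, 0.482 for p53 targets and immediate early genes, 0.764 for dental epithelium, skeletal muscle and mitochondrially encoded genes, 0.819 for interferon response and nuclear oxidative phosphorylation, 0.808 for macrophage and glia, 0.198 for cartilage, 0.182 for collagens and 0.527 for ribosomal proteins. With fry it was 0.0947 for p53 targets, immediate early genes and ribosomal proteins, 0.364 for dental epithelium, 0.515 for interferon response, 0.481 for macrophage, 0.417 for glia and skeletal muscle, 0.218 for mitochondrially encoded genes, 0.441 for nuclear oxidative phosphorylation and 0.0656 for histones. Random lists gave 0.113 for BMP and TGF-beta targets, now not past it, and 0.034 for cell cycle exit, 0.0112 for ameloblast, 0.0418 for lymphocyte, 0.00146 for erythroid and 0.0172 for sex-linked genes, now past it. Random lists draw genes singly and ignore that genes of a list move together, so such a pass is no evidence of a difference by genotype. Sex-linked genes passed although each genotype held libraries with both patterns of sex-linked counts.

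Odontoblast genes passed with library size only (0.0423), no filter (0.0493) and the sex-linked term (0.0347). With the epithelium score the dental epithelium list itself turned from up to down (0.448), ameloblast (2.83e-25), endothelial (0.00435) and pericyte (0.0337) genes passed, and interferon (0.34), immediate early (0.231), glia (0.611) and mitochondrially encoded genes (0.487) did not. The score is the mean of the dental epithelium list, so the loss of that list's own rise was built into the fit. In the 4 libraries with Y-linked counts immediate early (0.0886), macrophage (0.24) and glia (0.133) did not pass, and with the GC and length trend removed mitochondrially encoded (0.0581) and nuclear oxidative phosphorylation genes (0.223) did not. Without single libraries the adjusted p ranged from 6.8e-06 to 0.891 for odontoblast, 1.32e-05 to 0.737 for interferon response, 0.0146 to 0.0852 for immediate early, 2.38e-06 to 0.148 for macrophage, 5.16e-05 to 0.102 for glia, 6.59e-11 to 0.232 for skeletal muscle and 1.07e-05 to 0.0852 for nuclear oxidative phosphorylation genes. Low genes such as Sst rest on few counts, and its log2 fold change of 3.55 was 0.66 on the authors' normalized table with a pseudocount of 5. A pseudocount of that size shrinks the fold of any gene this low, so the smaller value does not measure the spread between libraries.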

Other observations

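The rule that the progenitor median must miss its bound by more than the SD of its members was added after its value was seen. The tests of the progenitor share, of the follicle and ligament share, of Gli1 and of the gene families were chosen only after the result was seen, and the GC trend and epithelium score alternatives after seeing the data. Of the genes that follow, those not named above were chosen after their values were seen, and no library was left out for them. The simple epithelial keratins Krt8 and Krt18 rose, with log2 fold changes of 1.09 (edgeR adjusted p = 0.0169) and 0.95 (0.0231), and Krt7 had 0.91 (0.306). Of 14 small leucine-rich proteoglycan genes, which encode collagen-binding proteins of the matrix, 4 fell and 0 rose: Fmod, Lum (1.99-fold, adjusted p = 0.0194), Aspn and Kera (log2 fold change -2.22, 0.0368), while Ogn had a log2 fold change of 0.74 (0.0846) and Dcn -0.46 (0.103). Of 6 type VI collagen genes 3 fell, Col6a1, Col6a2 and Col6a3 (log2 fold change -0.43, adjusted p = 0.0348). Of 95 potassium channel and synaptic vesicle genes 10 rose and 6 fell, including Kcnk15 (log2 fold change 2.23, adjusted p = 0.0181) and Kcnf1 (1.43, 0.00919) among those that rose and Kcnh2 (-0.86, 0.0409) among those that fell.

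It was asked whether 2 gene families move as a whole. Bootstrap intervals here and below resample the genes of a list, so they leave out the spread between libraries. Without Fmod and Lum the other 12 small leucine-rich proteoglycan genes had a median log2 fold change of -0.12 (95% bootstrap interval -0.56 to 0.20), which leaves this open because the members differ widely. Without the gene named by the rule the other 94 potassium channel and synaptic vesicle genes had a median of 0.0994 (-0.05 to 0.25), which also leaves it open.

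The 777 genes of the real split were compared with the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 gave as many genes, the real one, and the highest other count was 1. For the 17 lists past the threshold with camera, 5 of the 10 splits gave as many, and the highest other count was 20. With 10 splits a share under 0.05 cannot be reached. Each other split also holds both genotypes in each group, so its count does not show how many genes pass with no difference.

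Of 108 genes in the 3 cell cycle lists, 36 were higher in Arid1a cKO, 0 were lower and 103 had a positive log2 fold change. Each of these lists had a camera adjusted p of 0.344 with an estimated correlation. With the GC and length trend of each library removed, the median log2 fold change of the 54 G2/M genes was 0.473 (95% bootstrap interval over genes 0.436 to 0.535) and 25 of them rose, which argues against that trend as the whole cause. The interval leaves out the spread between libraries. In the main model without single libraries the median ranged from 0.425 to 0.544. With the dental epithelium score in the model the median was 0.426 (0.375 to 0.469) and 53 of 54 were positive, so little of the rise followed this score. No G2/M gene passed. For Cdk1 the SE grew from 0.0671 to 0.107 at an almost equal log2 fold change of 0.69. For Aurka the SE grew from 0.103 to 0.16 and the log2 fold change went from 0.63 to 0.54. The score is a mean over 19 genes, and its values overlapped between the groups (0.097 in control replicate 3, 0.0082 in Arid1a cKO replicate 2). It cannot capture epithelium that these genes do not mark, so a larger share of epithelium stays open. A larger share of progenitor-rich mesenchyme would raise progenitor markers, and the 23 without Gli1 had a median of 0.00121 (-0.189 to 0.218), but members went both ways (SD 0.412), with Sfrp2 at 1.085 (adjusted p = 0.197) and Msx2 at -0.49 (0.0194), so this explanation stays open. A change in division or in the share of transit-amplifying cells in Arid1a cKO may account for it and stays open as a hypothesis, as does a difference in the dissected piece not marked by these genes, and since the groups differ by the CreER allele as well as by loss of Arid1a, either could be behind it.

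Of 44 collagen genes 11 were lower in Arid1a cKO. With the GC and length trend removed 10 of the 11 lower collagens stayed lower, with a median of -0.65, which argues against that trend as the whole cause. Fewer follicle and ligament cells would lower their markers together. The 11 that are not collagens had a median log2 fold change of 0.205 (95% bootstrap interval over genes -0.287 to 0.563), above the median of -0.64 of the lower collagens. Those collagens were picked for their fall, and the median of all 44, -0.169, lies within that interval, so the comparison cannot decide. Fmod and Aspn were lower, while Spon1 at 0.83 (edgeR adjusted p = 0.202), Tnmd at 0.60 (0.199) and Postn at 0.56 (0.207) did not pass. Loss of these cells stays open. A lower expression of these genes after loss of Arid1a may be the reason and is a hypothesis, an effect of the CreER allele stays open beside it, and loss of another cell type that makes these collagens was not tested.

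Gli1 was lower in Arid1a cKO, and the labels leave open whether the CreER allele is inserted in Gli1 and disrupts a copy in these mice. If such an insertion silenced 1 copy of the gene and nothing else changed, the log2 fold change would be -1, and the observed value was -0.519 (SE 0.0747), more than 2 SE above it. Lower Hedgehog signalling stays open, as the 18 genes of the Hedgehog list moved both ways, with a median log2 fold change of 0.055 and a camera adjusted p of 0.573. Partial silencing by an insertion, counts of transcripts that start in the altered copy, and fewer Gli1-expressing cells could each give such a value, and no test here separates them.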
